A study of Mus musculus with 6 samples.

How the data were processed

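Total RNA from the colon mucosa of mice was measured on 1-colour (Cy3) bead arrays, 1 array per sample. There were 6 samples in 2 groups: 3 samples from wild type mice of strain C57BL/6 obtained from Taconic, and 3 samples from mice lacking microRNA-21 (miR-21 KO) on a C57BL/6 background that came from another laboratory. All were untreated. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says how many animals lie behind a sample or that the replicates are separate animals, so p-values measure the spread between these samples, part of which may be technical.

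The deposited probe table holds, per the file headers, a mean bead intensity on a linear scale, a detection p-value, a bead standard error and a number of beads for each of 25697 probes and each array. The intensity values were not normalized between arrays when the authors deposited them, since the array medians differ. The detection p-value compares a probe with the negative control beads of its array, per the file headers and the step size of the values. The bead standard errors and bead numbers (other units in the deposited table, per the file headers) were used only to describe the arrays: the median probe had 32 to 39 beads and a bead standard error of 2.55 to 3.11 percent of its intensity. A second deposited table holds log2 values that the authors had normalized between arrays, with 18010 of the probes. The submitters' processing notes name limma, with no version and no role, and the software that read the arrays is not given in the sources used here. The deposited log2 values and the values computed here from the intensities correlated at r of at least 0.9999 after rounding, across probes on each array, with a median difference of 0.04. The scale and the direction of the deposited values were settled in this way, and the rule by which its probes were kept was not. It held all 16388 probes detected on at least 1 array and 1622 detected on none.

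Median intensity was 111.2, 115 and 97 for WT replicates 1 to 3, and 109.3, 108.2 and 98.3 for KO replicates 1 to 3. The mean intensity was 3.20 to 4.20 times the median of undetected probes, and 50.4 to 54.6 percent of probes were detected (detection p-value under 0.05). The number of arrays limits the precision. WT replicate 3 and KO replicate 3 were the 2 dimmest arrays, 1 in each group.

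Intensities were normalized with neqc in limma 3.58.1 (R 4.3.3, statmod 1.5.0): normexp background correction with the negative control mean and SD inferred from the detection p-values, quantile normalization, an offset of 16 and log2. Probes detected on at least 3 of the 6 arrays entered the test, which left 13737 probes for 10380 symbols. Each probe was fitted with lmFit and eBayes, miR-21 KO minus WT, two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05 on the adjusted p. "Higher", "rose", "lower" and "fell" refer to miR-21 KO against WT and to that threshold. The fit used all 6 arrays with no covariate. A permutation of 3 arrays against 3 has a smallest p of 0.1, so single genes rest on the limma model.

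Where a probe was detected on no array of a group, its fold is a bound ("at least"): the mean of the group that detected it against, per array of the other group, the higher of the probe's own normalized value and the lowest normalized value among detected probes. Where some arrays of a group detected it, their number is given.

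Gene symbols were updated through a table of mouse genes (assembly GRCm38.p6), by Entrez ID for 23788 probes and by unversioned RefSeq accession for 685. The other 1224 probes kept the symbol of the deposited table. The files name no genome build, so no coordinates are printed, and the table served only for chromosomes and for which genes lie near one another. A gene with several probes is represented by the probe with the highest mean over all 6 arrays. Of 448 genes with several probes whose main probe passed the threshold, 273 had another tested probe that did not. For 6 symbols, probes passed in both directions.

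Before the data were examined, 39 gene lists (cell types, pathways and strain-dependent genes) were fixed from general knowledge. The 38 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Camera compares a list with the other genes. Fry tests a list's own genes, on balance in one direction or, in its mixed form, in either. With the preset correlation 19 lists passed, 7 higher and 12 lower. With an estimated correlation 0 passed, and the smallest adjusted p was 0.511. Fry called 4 lists in one direction and 33 in the mixed form.

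The genes named were set by a rule fixed before the data were examined. It takes the 15 largest changes in each direction past the threshold, 1 probe per symbol, curated names before clone names. It adds, among others, Mir21, Vmp1, Pdcd4, Spry1, Spry2, Reck, Timp3, Btg2, Tgfbr2, Smad7, Peli1, Il12a, Rhob, Nnt, Xist, Ddx3y and Eif2s3y, and from each list up to 4 members with the smallest p. Some genes that the rule names are not analysed here. Genes outside the rule are named only where the text says that they were chosen after their values were seen.

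On simulated arrays with the real means and spreads of the 13737 tested probes, 200 probes were changed in the KO arrays. The test recovered 196 of them at a log2 change of 2, with 7 false calls, and 125 at a log2 change of 1, with 5 false calls. At a log2 change of 0.58 it recovered 0. With 2000 probes changed by 1 it recovered 1762, and 4.50 percent of its calls were false. In simulated arrays with independent genes and no shifted list, camera called 0 lists. With the goblet cell list shifted by 0.5 it called 2 lists, that list and 1 that had not been shifted.

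The alternatives were other background corrections and normalizations, the deposited log2 table, other filters, other moderation, array weights, the replicate number as a block, other thresholds and gene rules, other list tests, and each array left out. Of the planned analyses, these were not run: the test of genes with a miR-21 seed match in the 3' UTR, for which transcript sequence was not used here, and the array slide as a block, since the slide is not given in the sources used here. A block for the 2 dimmer arrays and a fit to the 4 brighter arrays alone were added after the data were seen.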

Results

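Colon mucosa of wild type (WT) C57BL/6 mice (3 samples) and of mice lacking microRNA-21 (miR-21 KO, 3 samples) was profiled on bead arrays, with 1 sample per array. The series concerns the effect of microRNA-21 loss on colitis in mice, and these samples are from untreated animals. The comparison asks how the mucosal transcriptome differed between the 2 groups without induced disease. All WT mice were obtained from Taconic and all KO mice came from another laboratory. An effect of genotype therefore cannot be told apart from an effect of source in any result below. Arrays of the same group correlated at r = 0.981 to 0.990 across probes and arrays of different groups at r = 0.956 to 0.972. The first principal component held 59.1 percent of the variance and separated the groups, with WT replicate 2 the WT array nearest to the KO arrays.

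The array has no probe for Mir21 itself, so the deleted microRNA could not be measured. Vmp1, an autophagy gene whose transcript overlaps the microRNA, had 5 probes that moved in different directions. Probes ILMN_2591777 and ILMN_2591781 were detected on all 3 WT arrays and on 0 of 3 KO arrays, at least 3.15-fold and 3.31-fold lower in KO (adjusted p = 0.000209 and 0.000228). Probe ILMN_2861787 was 12.8-fold higher in KO (log2 difference 3.68 ± 0.18 (SE), n = 3 per group, adjusted p = 6.44e-06), and was detected on all 6 arrays. The brightest probe, ILMN_2767635, was 1.47-fold lower (log2 difference -0.55 ± 0.14, adjusted p = 0.0322), and ILMN_2616768 did not pass the threshold (-0.27 ± 0.18, adjusted p = 0.336). Where these probes lie relative to the deleted segment was not analysed here, so they do not by themselves check the labels.

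**Figure D1:**
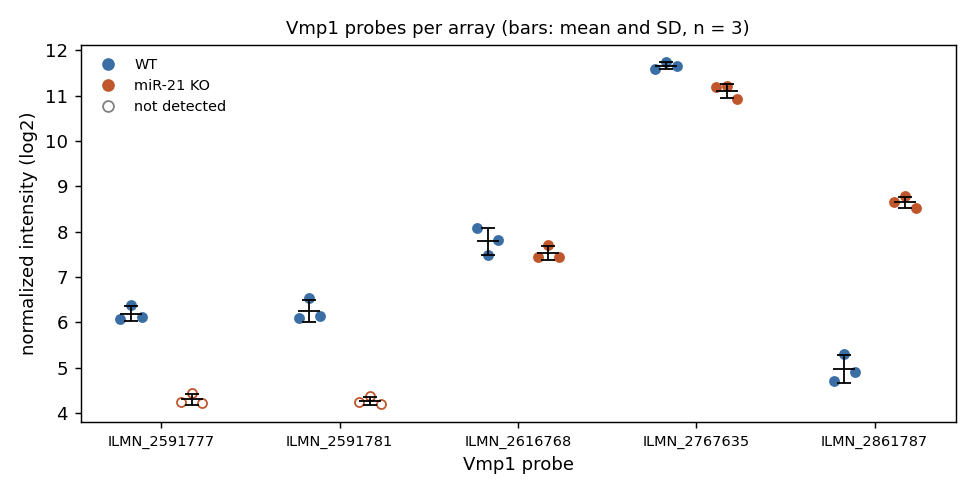
Normalized intensity (log2) of the 5 Vmp1 probes on each array, with WT in blue and miR-21 KO in orange; open points were not detected, and bars give the mean and SD of 3 arrays. ILMN_2591777 and ILMN_2591781 were detected on WT arrays alone, and ILMN_2861787 rose from a mean of 4.97 in WT to 8.65 in KO.

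Between the genotypes 2071 of 13737 probes differed, 1034 higher and 1037 lower in KO, which is 15.1 percent of those tested. Counted by the main probe of each gene, 836 genes were higher and 791 lower. At least a 2-fold change was found for 186 probes higher and 296 lower, and the median change of the called probes was 1.68-fold. All KO arrays lay on one side of all WT arrays for 2068 of the called probes, and for 36.4 percent of all tested probes, where chance gives 10 percent. With median scaling in place of quantile normalization 193 probes were higher and 343 lower. The count fell to 895 without WT replicate 1, 902 without WT replicate 3, 920 without KO replicate 1 and 460 without KO replicate 2, and was 2116 without WT replicate 2 and 1770 without KO replicate 3. It was 3772 with array weights and 839 on the 4 brighter arrays, a fit added after the data were seen.

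Among the 15 largest increases, Ang4, an antimicrobial ribonuclease of Paneth and goblet cells, was 17.8-fold higher (log2 difference 4.16 ± 0.72, adjusted p = 0.009996), and Retnlb, a goblet cell product induced in helminth infection, was 6.65-fold higher (2.73 ± 0.74, adjusted p = 0.0386). Best2, a channel of colonic goblet cells, was 6.21-fold higher (2.64 ± 0.28, adjusted p = 0.00129). Lpo, encoding lactoperoxidase, was detected on 0 of 3 WT arrays and was at least 14.0-fold higher in KO (adjusted p = 7.97e-07). The largest increase of all was for H2-Bl, a nonclassical MHC class I gene, at 38.9-fold with 2 of 3 WT arrays detecting it (5.28 ± 0.14). Rgs5, a pericyte gene, was 6.86-fold higher, Timmdc1 5.11-fold and Gbp2b 6.96-fold. Cfd, Car3, Cyp2e1, Adipoq, Cidec, Thrsp and Pon1 complete the 15, from a log2 difference of 2.28 for Pon1 to 4.32 for Cfd; 2 of 3 WT arrays detected Car3, Cyp2e1, Cidec and Pon1, and 1 of 3 detected Thrsp. Several of these vary widely within a group: Gbp2b read 5.71 on KO replicate 1 against 9.60 and 8.98 on the other KO arrays, and its WT mean was 5.30.

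Among the 15 largest decreases, Ido1, the tryptophan-degrading enzyme, was 12.4-fold lower (-3.63 ± 0.57, adjusted p = 0.00730). Ubd, a ubiquitin-like protein, was 11.2-fold lower (-3.48 ± 0.61, adjusted p = 0.0103), and Trim30a was 8.29-fold lower with 1 of 3 KO arrays detecting it (-3.05 ± 0.45). The cell cycle inhibitor Cdkn2b fell 10.2-fold (-3.35 ± 0.14, adjusted p = 3.03e-06) and the cyclin gene Ccng2 22.0-fold (-4.46 ± 0.21, adjusted p = 6.21e-06). The neighbouring whey acidic protein genes Wfdc17 and Wfdc18 fell 9.85-fold and 7.21-fold. Ctsc, a lysosomal protease, fell 9.54-fold on its main probe, and its other 2 tested probes fell as well (log2 differences -3.00 and -3.36). Zfp68 fell 8.32-fold on its main probe and 17.8-fold on ILMN_2455192, which 1 of 3 KO arrays detected, while its other tested probe, ILMN_3133085, was 1.43-fold higher. Cops8 (9.39-fold, detected on 2 of 3 KO arrays), Picalm (7.94-fold), Zan (7.13-fold), the B cell genes Fcmr (6.57-fold) and Fcrla (6.54-fold), and the Y-linked Eif2s3y complete the 15. Leaving out single arrays or changing the processing (18 alternatives, 17 for genes not detected on all 6 arrays) ended the call of Gbp2b in 12 of them, of Retnlb in 10, of Adipoq in 9, of Cfd in 8, of Cyp2e1 and Picalm in 5 each and of Cidec in 4. Among genes named from the lists or near Mir21, the call was lost for Car4 and Ciita in 11, for Hoxd12, Creb3l4 and Il1r2 in 10, for Uty, Tef, Nr1d2 and Cxcl10 in 9, and for the brightest Vmp1 probe, Pmvk, Srebf2, Dbp, Usp2, Aif1 and Csrp1 in 8.

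Published targets of miR-21 were examined as a list. Of 30 measured targets 4 were higher and 1 lower, the same numbers when adjusted over the list alone, and the list did not pass (median log2 difference 0.26, camera adjusted p = 0.116). Nfib was 2.06-fold higher (1.04 ± 0.19, adjusted p = 0.0108), Arhgap24, a Rac regulator, 1.94-fold (0.95 ± 0.18), the chromatin remodelling gene Pbrm1 1.74-fold (0.80 ± 0.20), and Reck, a matrix protease inhibitor, by a log2 difference of 0.58 ± 0.17 (adjusted p = 0.0463, lost in 10 of the alternatives). Rasgrp1, a T cell signalling gene, was 2.59-fold lower (-1.37 ± 0.30). The call was lost in 7 of the alternatives for Pbrm1, in 6 for Rasgrp1 and in 2 each for Nfib and Arhgap24. The tumour suppressor Pdcd4 had a log2 difference of 0.82 ± 0.26 (adjusted p = 0.0601) and Timp3 of 0.57 ± 0.19 (adjusted p = 0.0723), neither past the threshold. Rhob (-0.28 ± 0.14), Tgfbr2 (0.05 ± 0.14) and Peli1 (0.09 ± 0.16) did not pass either. Spry1 had no probe, and the probes of Spry2, Btg2, Smad7 and Il12a were detected on too few arrays to be tested.

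Lymphocyte genes were lower in KO. In the B and plasma cell list 11 of 16 measured members fell and 0 rose (11 adjusted over the list alone; median log2 difference -0.78, adjusted p = 3.3e-05, and adjusted p = 0.618 with an estimated correlation). Fcmr, an IgM receptor, fell 6.57-fold (-2.72 ± 0.27), Blk, a B cell kinase, 5.06-fold with 1 of 3 KO arrays detecting it (-2.34 ± 0.37), and the follicle-homing receptor Cxcr5 4.32-fold with 2 of 3 KO arrays detecting it (-2.11 ± 0.39). In the T and NK cell list 8 of 18 fell and 0 rose (11 fell adjusted over the list alone; median -0.80, adjusted p = 3.3e-05, and adjusted p = 0.618 with an estimated correlation). The NK receptor Klrd1 fell 3.43-fold (-1.78 ± 0.19), Il7r 2.23-fold (-1.16 ± 0.20) and Nkg7 1.85-fold with 2 of 3 KO arrays detecting it (-0.89 ± 0.19). Levels also varied within WT: Cd79b, a B cell receptor subunit chosen after its values were seen, read 10.98, 8.01 and 9.44 on WT replicates 1 to 3 and 6.67, 6.55 and 7.26 on the KO arrays.

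**Figure D2:**
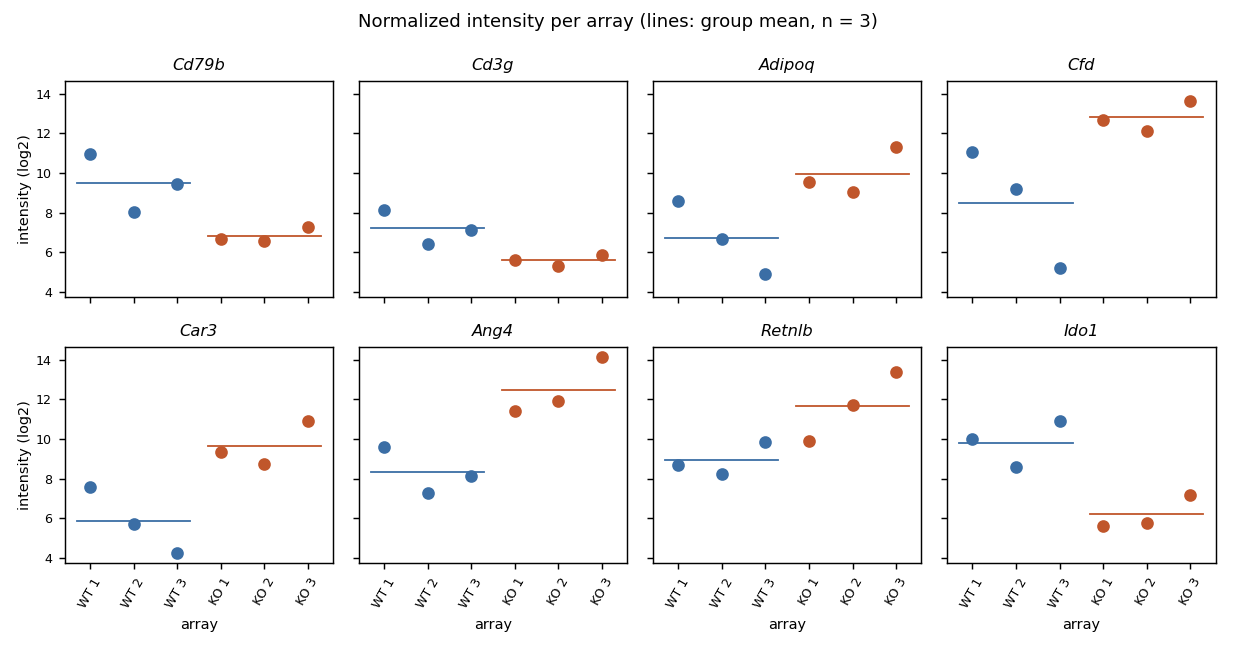
Normalized intensity (log2) of 8 genes on each of the 6 arrays, WT in blue and miR-21 KO in orange, with lines at the group means (n = 3). Cd79b and Cd3g mark lymphocytes and were chosen after their values were seen; Adipoq, Cfd and Car3 mark fat cells, with Adipoq at 8.58, 6.68 and 4.91 on the WT arrays; Ang4, Retnlb and Ido1 are among the largest changes.

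Other immune lists were lower as well, and were not shown to be changes separate from those of the lymphocyte lists. Among inflammatory cytokines and chemokines 7 of 16 fell and 0 rose (11 fell adjusted over the list alone; median -0.72, adjusted p = 3.3e-05, and adjusted p = 0.511 with an estimated correlation). Ccl5 fell 2.52-fold (-1.33 ± 0.19), Ccl28, an epithelial chemokine for plasma cells, 2.38-fold (-1.25 ± 0.25), Il1b 2.35-fold (-1.23 ± 0.24) and Cxcl10 2.02-fold (-1.01 ± 0.25). Of 28 interferon response genes 3 fell and 0 rose (3 adjusted over the list alone; median -0.37, adjusted p = 0.000331, and adjusted p = 0.628 with an estimated correlation). They were Cxcl10, Gbp2 (2.20-fold) and the transcription factor Irf1 (1.68-fold on its main probe, with all 5 of its probes lower), and Rtp4 had -0.79 ± 0.24 (adjusted p = 0.0579). By the mean of the listed genes (log2, each gene centred on its mean over the arrays), WT replicate 2 lay within the range of the KO arrays for the interferon list (-0.27, against 0.67 and 0.36 on the other WT arrays and -0.42, -0.35 and 0.01 on the KO arrays) and for MHC class II (-0.28, against -0.42, -0.45 and -0.03). Of 10 MHC class II genes 3 fell (4 adjusted over the list alone; adjusted p = 0.0209, and adjusted p = 0.628 with an estimated correlation): H2-Ob, a B cell class II chain, by 4.18-fold, the class II transactivator Ciita by 1.86-fold and the protease Ctss by 1.74-fold, with H2-Oa at -1.33 ± 0.47 (adjusted p = 0.0870). That call was lost without WT replicate 1 (adjusted p = 0.129), WT replicate 3 (0.0576) or KO replicate 2 (0.0537).

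For macrophages and monocytes, where WT replicate 2 (-0.09) again lay within the range of the KO arrays (-0.36, -0.24 and 0.04), 5 of 20 genes fell and 0 rose (6 fell adjusted over the list alone; median -0.27, adjusted p = 0.0199, and adjusted p = 0.628 with an estimated correlation). Tyrobp fell 2.51-fold (-1.32 ± 0.25), Aif1 1.90-fold, Ms4a7 1.73-fold and the mannose receptor Mrc1 1.71-fold; another Ms4a7 probe did not pass (-0.31, adjusted p = 0.202). The call was lost without WT replicate 3 (adjusted p = 0.219) or KO replicate 1 (0.0691), with no filter on dim probes (0.0501) and on the 4 brighter arrays (0.0520). In the neutrophil list 1 of 6 fell (4 adjusted over the list alone; adjusted p = 0.0163, 0.1001 with no filter on dim probes, and adjusted p = 0.583 with an estimated correlation). Il1r2 was detected on 0 of 3 KO arrays and was at least 1.39-fold lower, and S100a8 (-1.88 ± 0.56, adjusted p = 0.0527), S100a9 (-1.51 ± 0.48, adjusted p = 0.0620, detected on 2 of 3 KO arrays) and Mmp9 (-0.49 ± 0.19, adjusted p = 0.110) did not pass.

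Genes of stromal cells and fat were higher in KO. Of 30 fibroblast and extracellular matrix genes 11 rose and 0 fell (17 rose adjusted over the list alone; median 0.51, adjusted p = 3.3e-05, and adjusted p = 0.628 with an estimated correlation). The collagen genes Col15a1 (3.02-fold, 1.60 ± 0.23), Col4a2 (2.08-fold, 1.06 ± 0.21) and Col5a1 (1.86-fold, 0.90 ± 0.18) and the matrix protein gene Fbln2 (2.47-fold, 1.31 ± 0.19) were among them. Endothelial genes rose for 7 of 17 members (10 rose and 1 fell adjusted over the list alone; median 0.59, adjusted p = 0.000488, and adjusted p = 0.618 with an estimated correlation), with Egfl7 3.01-fold, Cldn5 2.36-fold, the VEGF receptor Flt1 2.02-fold and Eng 1.66-fold higher. Of the other tested Egfl7 probes ILMN_1215919 was higher (0.90, adjusted p = 0.0135, detected on 2 of 3 WT arrays) and ILMN_2631417 did not pass (-0.17, adjusted p = 0.570, detected on 2 of 3 WT and 1 of 3 KO arrays), nor did another Fbln2 probe (0.56, adjusted p = 0.0729). Smooth muscle genes rose for 2 of 19 (8 adjusted over the list alone; median 0.71, adjusted p = 0.000400, and adjusted p = 0.628 with an estimated correlation). These were Cnn1 (1.77-fold) and Csrp1 (1.87-fold), and Tagln had 0.84 ± 0.25 (adjusted p = 0.0527) and Mylk 0.80 ± 0.26 (adjusted p = 0.0674). By the mean of the smooth muscle genes WT replicate 2 (0.06) lay above KO replicate 3 (0.00).

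Adipocyte genes had the largest median difference, 1.91, with 7 of 10 higher and 0 lower, also adjusted over the list alone (adjusted p = 0.000400, and adjusted p = 0.618 with an estimated correlation). Plin4, a lipid droplet protein, rose 4.05-fold (2.02 ± 0.30), leptin (Lep) 3.42-fold with 2 of 3 WT arrays detecting it (1.77 ± 0.28), Cidec by a log2 difference of 2.72 ± 0.54 and Car3 14.2-fold (3.83 ± 0.77), both also detected on 2 of 3 WT arrays. The fat cell hormone Adipoq ranged from 4.91 to 8.58 among WT arrays and from 9.03 to 11.30 among KO arrays.

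**Figure D3:**
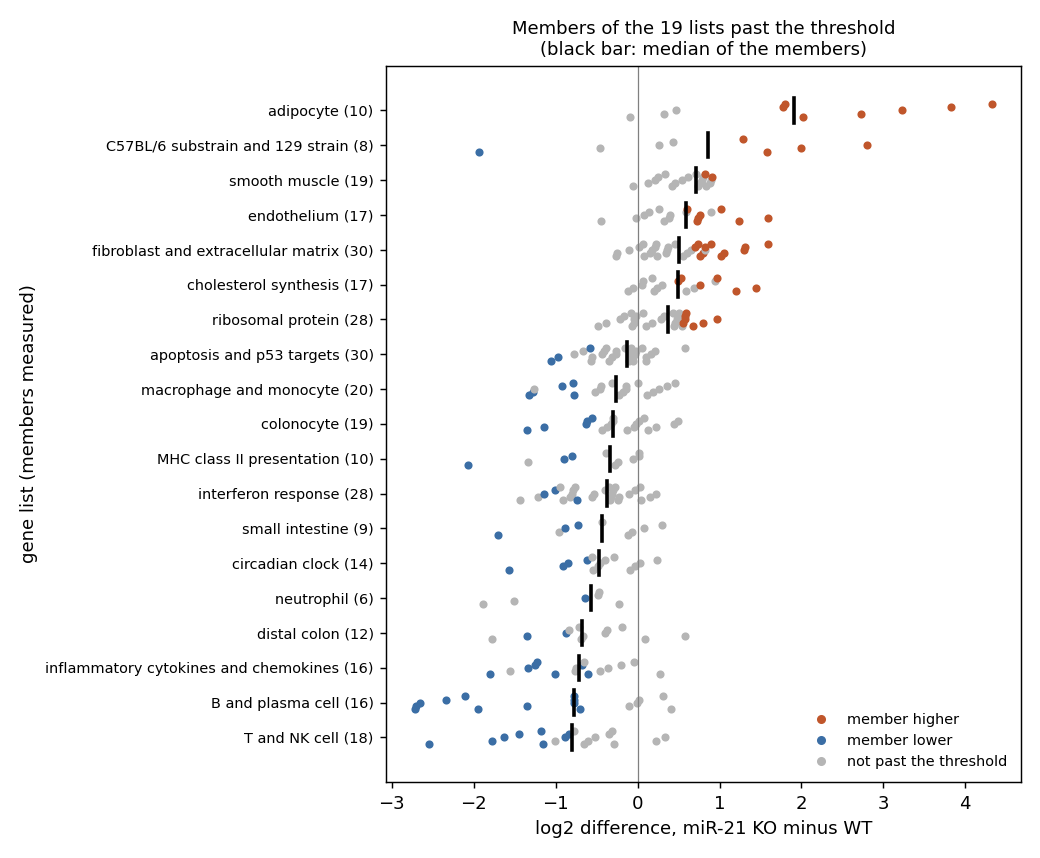
Log2 difference (miR-21 KO minus WT) of each measured member of the 19 gene lists that passed with the preset correlation, with a black bar at each list's median and the number of measured members in brackets. The medians run from -0.80 for T and NK cells to 1.91 for adipocytes, and none of these lists passed with an estimated correlation.

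Mature colonocyte genes were lower in KO. Of 19 members 5 fell and 0 rose (6 fell and 1 rose adjusted over the list alone; median -0.30, adjusted p = 0.0199, and adjusted p = 0.511 with an estimated correlation). Ceacam20 fell 2.56-fold (-1.35 ± 0.18), the microvillus protein villin (Vil1) 2.21-fold (-1.15 ± 0.17), the surface keratin Krt20 1.55-fold and the carbonic anhydrase Car4 1.47-fold. With cyclic loess normalization the list had an adjusted p of 0.0590. Small intestine genes fell for 3 of 9 members (4 adjusted over the list alone; adjusted p = 0.0393, and adjusted p = 0.618 with an estimated correlation): the peptide transporter Slc15a1 by 3.27-fold and the meprins Mep1a and Mep1b by 1.86-fold and 1.65-fold, with Rbp2 at -0.96 ± 0.29 (adjusted p = 0.0551). The call of that list was lost in several alternatives, among them leaving out WT replicate 2 (0.0553), WT replicate 3 (0.101) or KO replicate 3 (0.0714). In the distal colon list 2 of 12 fell (adjusted over the list alone 2 fell and 1 rose; median -0.68, adjusted p = 0.0138, and adjusted p = 0.618 with an estimated correlation), the homeobox genes Hoxd10 (2.55-fold) and Hoxd12 (1.84-fold). Insl5 had 0.57 ± 0.17 (adjusted p = 0.0519) and Scnn1g -1.77 ± 0.63 (adjusted p = 0.0869), and the call was lost without KO replicate 3 (adjusted p = 0.0645) and on the 4 brighter arrays (0.119).

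Goblet cell and defence genes moved both ways, and neither list passed with camera. Both passed fry in its mixed form (adjusted p = 3.64e-05 and 0.000255), as did 33 of the 38 lists tested. Of 18 goblet cell genes 3 rose and 1 fell, also adjusted over the list alone (median 0.11, adjusted p = 0.168). St6galnac1, a mucin sialyltransferase, was detected on 0 of 3 WT arrays and was at least 2.96-fold higher (adjusted p = 9.16e-05), Retnlb rose 6.65-fold and Creb3l4 1.65-fold, while Ccl9 fell 1.90-fold. Of 18 antimicrobial and epithelial defence genes 3 rose and 3 fell (3 and 8 adjusted over the list alone; adjusted p = 0.150). Ang4, Retnlb and the immunoglobulin transporter Pigr (1.65-fold, 0.73 ± 0.18) were higher, and Ido1 and the lectin Reg3b (2.07-fold, -1.05 ± 0.23) were lower. Crypt base genes did not pass for any of 10 members (0 at the threshold with limma and also adjusted over the list alone; median 0.15, list adjusted p = 0.574), with Lrig1 at 0.48 ± 0.18, Tcf7 at -0.37 ± 0.14 (detected on 2 of 3 KO arrays), Lgr5 at 0.53 ± 0.21 (detected on 1 of 3 WT arrays) and Ephb2 at 0.62 ± 0.29 (detected on 2 of 3 WT arrays). Of 26 proliferation genes 0 passed with limma, also adjusted over the list alone (median 0.16, list adjusted p = 0.588).

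Cholesterol synthesis genes were higher in KO, with 6 of 17 up and 0 down (7 up adjusted over the list alone; median 0.49, adjusted p = 0.00287, and adjusted p = 0.628 with an estimated correlation). The mevalonate pathway enzymes Mvd and Pmvk rose 2.31-fold (1.21 ± 0.20) and 1.70-fold, the sterol carrier Stard4 1.96-fold (0.97 ± 0.15) and the sterol-sensing regulator Srebf2 1.45-fold. By the mean of these genes WT replicate 3 (-0.04) lay above KO replicate 1 (-0.09). Circadian clock genes were lower, with 4 of 14 down and 0 up (5 down adjusted over the list alone; median -0.47, adjusted p = 0.00468, and adjusted p = 0.628 with an estimated correlation). The clock output factors Dbp and Tef fell 2.98-fold (-1.58 ± 0.40) and 1.88-fold, Nr1d2 1.81-fold (another Nr1d2 probe had -0.26, adjusted p = 0.302, detected on 2 of 3 WT and 1 of 3 KO arrays) and Usp2 1.53-fold. On the 4 brighter arrays the clock list had an adjusted p of 0.119. By the mean of the clock genes WT replicate 1 (-0.0162) and KO replicate 1 (-0.0166) were nearly equal.

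Apoptosis genes and p53 targets fell for 3 of 30 members, also adjusted over the list alone (median -0.13, adjusted p = 0.00645, and adjusted p = 0.511 with an estimated correlation): the proapoptotic BH3 genes Bid (1.96-fold, -0.97 ± 0.14), Pmaip1 (2.07-fold, -1.05 ± 0.23) and Bbc3 (-0.58 ± 0.16). The Bbc3 call was lost in 8 of the 18 alternatives, and its other 2 tested probes did not pass (ILMN_2690620 0.26, adjusted p = 0.319, detected on 2 of 3 WT arrays, and ILMN_2690621, detected on 0 of 3 WT arrays and at least 1.06-fold higher in KO, adjusted p = 0.0597). Ribosomal protein genes rose for 7 of 28 members and fell for 0 (13 up and 2 down adjusted over the list alone; median 0.37, adjusted p = 0.0120, and adjusted p = 0.628 with an estimated correlation), with Rps9 1.95-fold, Rps15 1.74-fold and Rpl28 1.60-fold higher. The ribosomal call was lost with median scaling (adjusted p = 0.572) and on the 4 brighter arrays (0.0520).

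Genes known to differ between C57BL/6 substrains or between C57BL/6 and other strains used for gene targeting were changed in both directions. Of 8 measured members 4 rose and 1 fell (5 rose and 1 fell adjusted over the list alone; median 0.86, adjusted p = 0.0199, and adjusted p = 0.511 with an estimated correlation). With fry the list passed in one direction (adjusted p = 0.0343) and in the mixed form (adjusted p = 1.42e-05). The mixed value was the smallest of the 38 lists tested, of which 33 passed in that form. Ide, the insulin-degrading enzyme, was 2.99-fold higher (1.58 ± 0.14, adjusted p = 0.000588), Entpd4 2.43-fold (1.28 ± 0.17), Erdr1 3.98-fold with 2 of 3 WT arrays detecting it (1.99 ± 0.29) and Gbp2b 6.96-fold, and Trim30d was 3.83-fold lower (-1.94 ± 0.39). The call was lost among probes detected on all 6 arrays (adjusted p = 0.114), without WT replicate 2 (0.0538) and on the 4 brighter arrays (0.0706). The 3 probes of Nnt, a mitochondrial gene deleted in some C57BL/6 substrains, were not detected on any array of either group.

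Sex-linked genes were read on all arrays. Xist, expressed from the inactive X chromosome, was not detected on any of the 6 arrays with either of its 2 probes. Kdm5d and Uty on the Y chromosome were detected on all 6. Ddx3y, also Y-linked, was detected on all 6 with 1 of its 3 probes and on none with the others. Eif2s3y, also on the Y chromosome, was detected on 3 of 3 WT arrays and 1 of 3 KO arrays and was 38.0-fold lower in KO (-5.25 ± 0.18, adjusted p = 6.94e-07). Uty was 1.54-fold lower (-0.62 ± 0.16, adjusted p = 0.0345), and Kdm5d (-0.39 ± 0.18) and Ddx3y (0.40 ± 0.27) did not pass. With 4 measured members this list was not tested.

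Genes near the deleted microRNA were compared with the rest of the genome. Within 20 Mb of Mir21 on chromosome 11, 68 of 423 genes were called (16.1 percent) against 15.8 percent of 9398 genes elsewhere (odds ratio 1.02, two-sided Fisher's exact p = 0.892). Over the whole of chromosome 11 the odds ratio was 1.07 (Fisher's exact p = 0.489). Within 5 Mb, 17 of 62 genes were called (27.4 percent) against 15.8 percent of 9759 elsewhere (odds ratio 2.02, 95% interval 1.08 to 3.61, Fisher's exact p = 0.0213), the only 1 of these 3 windows past 0.05 before any adjustment for their number. Genes of that window include Lpo, Wfdc17, Wfdc18, Ccl5, Car4 and Vmp1. Neighbouring genes are not independent of one another.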

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

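The 4 brighter arrays and the block of the dimmer arrays were chosen after the result was seen. With 3 arrays per group the number of called probes depends on single arrays and on the spread estimate: against 2071 in the analysis reported, leaving out 1 array gave 460 to 2116. In 18 settings no named gene that was called in either analysis had the opposite sign in the other, though some genes never called changed sign around 0, such as Tgfbr2 (0.05, lowest -0.08). Of 2520 values of called named genes 1973 stayed called; 39 of 141 called named genes stayed called in every setting that tested them, and genes not detected on all 6 arrays had no value in the setting that requires it. Most list calls rest on the preset correlation, and 0 lists passed with an estimated correlation. Fry in one direction also called 4 of the lists. These were C57BL/6 substrain and other strain (fry adjusted p = 0.0343), and inflammatory cytokines and chemokines, apoptosis and p53 targets, and colonocyte (0.0470 each).

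Counts of probes called, higher, lower, and genes called were 536, 193, 343 and 410 with median scaling; 3772, 1959, 1813 and 2953 with array weights; 839, 367, 472 and 647 on the 4 brighter arrays; and 3423, 1755, 1668 and 2673 at an adjusted p of 0.10. Leaving out 1 array gave 895, 409, 486 and 693 (WT replicate 1), 2116, 1053, 1063 and 1649 (WT replicate 2), 902, 429, 473 and 713 (WT replicate 3), 920, 462, 458 and 711 (miR-21 KO replicate 1), and 460, 218, 242 and 354 (miR-21 KO replicate 2). The replicate number as a block gave 2154 probes, 1833 of them shared, and the block of the dimmer arrays gave 2264. Residuals of same-numbered arrays correlated weakly (r 0.00686, 0.155 and 0.0558), against -0.125 to 0.0781 for differently numbered arrays of the 2 groups. These values are too few to decide whether same-numbered arrays pair.

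List calls lost, with adjusted p: ribosomal protein 0.572 (median scaling); colonocyte 0.0590 (cyclic loess); macrophage and monocyte 0.0501 and neutrophil 0.1001 (no filter on dim probes); C57BL/6 substrain and other strain 0.114 (detected on all 6 arrays); small intestine 0.0568 (array weights) and 0.0588 (mean of the gene's probes). On the 4 brighter arrays: C57BL/6 substrain and other strain 0.0706, circadian clock 0.119, distal colon 0.119, macrophage and monocyte 0.0520, ribosomal protein 0.0520, small intestine 0.157. Over the arrays left out, the adjusted p ran from 0.000140 to 0.129 for MHC class II presentation, 0.0156 to 0.101 for small intestine, 0.000923 to 0.219 for macrophage and monocyte, 0.00448 to 0.0645 for distal colon and 0.00592 to 0.0538 for C57BL/6 substrain and other strain.

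With an estimated correlation the adjusted p was 0.511 for apoptosis and p53 targets, C57BL/6 substrain and other strain, colonocyte, and inflammatory cytokines and chemokines; 0.583 for neutrophil; 0.618 for adipocyte, B and plasma cell, distal colon, endothelium, small intestine, and T and NK cell; and 0.628 for cholesterol synthesis, circadian clock, fibroblast and extracellular matrix, interferon response, macrophage and monocyte, MHC class II presentation, ribosomal protein, and smooth muscle. With fry it was 0.0737 for adipocyte, B and plasma cell, endothelium, fibroblast and extracellular matrix, neutrophil, ribosomal protein, and small intestine, 0.0883 for T and NK cell, 0.0943 for distal colon, 0.123 for circadian clock, 0.132 for cholesterol synthesis, 0.178 for smooth muscle, 0.263 for interferon response, 0.266 for macrophage and monocyte, and 0.355 for MHC class II presentation. The position of changed genes on the chromosome of Mir21 gave a p of 0.0213 with the 5 Mb window, against 0.892 with 20 Mb.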

Other observations

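Several lists that the report does not describe held members that moved in opposite directions, and none of these lists passed with camera. Those of this paragraph passed fry in its mixed form (adjusted p from 2.06e-05 to 0.00425), as did 33 of the 38 lists tested. Of 25 xenobiotic metabolism genes 2 rose and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.446), with Aldh1a1, a retinoic acid-producing enzyme, 2.01-fold higher and Fmo5 2.25-fold, the carboxylesterases Ces2e 2.41-fold and Ces1f 2.07-fold lower. Of 20 unfolded protein response genes 4 rose and 1 fell, also adjusted over the list alone (0.321), with the goblet cell stress sensor Ern2 2.12-fold, Pdia3 1.56-fold and Sel1l 1.42-fold higher (2 other Sel1l probes did not pass) and Dnajb9 1.63-fold lower. Of 17 heat shock genes 4 rose and 3 fell, also adjusted over the list alone (0.388): Hspb1 rose 2.50-fold and the collagen chaperone Serpinh1 2.30-fold, and Chordc1 fell 2.09-fold and Dnaja1 1.66-fold. Of 18 immediate early genes 1 rose and 2 fell, also adjusted over the list alone (0.588): Egr1 was 1.94-fold higher, and Gadd45b 2.63-fold and Atf3 2.07-fold lower. In the TGF beta and BMP list 2 of 23 rose, Bmp4 (2.04-fold) and Tgfbi (1.75-fold), and 2 fell, Smad2 (1.62-fold) and Skil (1.47-fold), also adjusted over the list alone (0.595). For tight junctions and adhesion, Cldn5 and Cldn2 (1.77-fold) rose and Cldn4 (1.61-fold) and Ocln (1.46-fold) fell among 23 (3 and 3 adjusted over the list alone; 0.375).

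Among cell types with few cells, the hormone genes Gcg (2.11-fold higher) and Tph1 (1.97-fold lower) moved apart within 14 enteroendocrine genes (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.590), as did Ptgs1 (1.70-fold higher) and Hpgds (1.57-fold lower) within 8 tuft cell genes (1 and 1; 0.590). Of 12 enteric glia and neuron genes 1 rose and 0 fell, also adjusted over the list alone (0.767). The mast cell protease Cma1 rose 2.38-fold in 7 mast cell and eosinophil genes (1 and 0; 0.789) and the elastase Cela1 2.89-fold in 6 pancreatic acinar genes (1 and 0; 0.588). In the glia and mast cell lists the median was negative and the mean and the test positive. Of 6 erythroid genes Hbb-b1 was 3.34-fold lower and Hbb-b2 was detected on 0 of 3 WT arrays and at least 2.57-fold higher (1 and 1; 0.836), and here the median and mean were positive and the test negative. Within 43 oxidative phosphorylation genes 5 rose and 3 fell (6 and 5 adjusted over the list alone; 0.588), Ndufb10 by 2.19-fold up and Cox7b by 2.43-fold down among them, and within 18 fatty acid oxidation genes 2 rose and 2 fell (2 and 3; 0.588), Angptl4 by 2.32-fold up and Acadl by 2.45-fold down. Under the 18 alternatives of the sensitivity analysis the call was lost for Angptl4 and Hpgds in 10, for Bmp4, Skil, Cldn4 and Ocln in 9, and for Sel1l and Ces1f in 8.

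Of the tests below, those on neighbouring genes, on the amount of lymphoid tissue, on the amount of fat and on the 4 brighter arrays were chosen after the result was seen. The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2071 called probes and the highest other split 0, so 1 split of 10 gave as many. For the gene lists with the preset correlation the real split gave 19 and the highest other split 17, the one that sets WT replicates 1 and 3 and KO replicate 3 against the rest, and again 1 split gave as many. Every other split sets 2 WT arrays and 1 KO array against the rest, so each keeps part of the genotype contrast. The 3 that keep WT replicates 1 and 3 together called 16, 16 and 17 lists, and the remaining 6 called 6 to 12.

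The lymphocyte lists were lower and the adipocyte list higher in miR-21 KO. The 2 dimmer arrays, 1 in each group, are argued against as the only source. On the 4 brighter arrays the median log2 difference of the B and T cell genes was -0.94, against -0.78 on all 6. That of the adipocyte genes was 1.35, against 1.91. By the mean of the adipocyte genes, WT replicate 3 was the lowest WT array (-1.87) and KO replicate 3 the highest KO array (1.78), so the dimmer arrays widen that difference. The amount of lymphoid tissue or of fat in the sampled piece could differ too, and the tests made of this decide nothing: 88.2 percent of the 34 B and T cell genes were higher in WT replicate 1 than in WT replicate 2, and 80 percent of the 10 adipocyte genes were higher in WT replicate 1 than in WT replicate 3, but these arrays had the highest and lowest WT means of those genes, so the outcome followed from the choice. Other lists may reflect the sampled piece too, which was not tested. By list means, WT replicates 1 to 3 read 1.15, 0.04 and 0.52 for B and plasma cells and 0.62, 0.08 and 0.47 for cytokines. The order was reversed for smooth muscle (-0.70, 0.06 and -0.24) and fibroblasts (-0.52, -0.03 and -0.24). It was also reversed for neutrophils (0.10, 0.84 and 0.37), whose list was lower in KO. Endothelium and macrophages kept neither order. A genotype effect on lymphocytes or fat stays open. It cannot be told apart from an effect of source, and no cell counts or histology were analysed here.

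Called genes with at least a 2-fold change lay near one another more often than in permuted gene orders: among 361 such genes there were 98 pairs within 5 measured genes, against a permuted median of 65 (permutation p = 0.000999, the smallest that 1000 permutations can give). Listed genes and shared name stems longer than 1 letter were argued against as the whole reason. Without listed genes and further genes of the same name stem, the pairs were still 1.48 times the permuted median (40 pairs against 27, 95th percentile 35, permutation p = 0.00799). Neighbours with shared expression outside the lists stayed in, so this does not argue against co-regulation. Unlisted genes of families with a 1-letter stem, such as H2, or with stems that differ by letters stayed in too. Gene families as a whole are therefore not argued against. A hypothesis is that the KO mice carry chromosome segments of another strain, and the 40 pairs may reflect that, co-regulation or the remaining families. However, only 1 window of 25 genes passed the permuted 95th percentile of the largest window (7 changed genes against 6). It lay on chromosome 11 and was the only 1 with all placed genes as well as with the genes left out. The genes left out included the listed strain genes, so the 40 pairs could not draw on them. Windows on several chromosomes had been required. The changed genes of the chromosome 11 window were Camk2b, Myo1g, Igfbp3, Upp1, Ikzf1, Fignl1 and Plek (named after their values were seen). Segments present in some KO mice only could give Ctsc and Picalm, which lie 7 measured genes apart on chromosome 7, their shared order: KO replicate 1 read 9.38 and 8.36, against 6.89 and 5.80 on replicate 2 and 7.02 and 5.54 on replicate 3. The 10 genes spread in this way formed 0 pairs within 5 genes where the permuted median was also 0. By the rule first written this counted against such segments; the reading was changed to undecided after the value was seen, because 10 genes could hardly have formed pairs.

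Some of the largest changes may be losses of probe binding at a sequence variant and not changes of the mRNA. Of the 44 comparisons with another tested probe of a gene changed at least 4-fold, 65.9 percent moved the same way by at least 0.5 of the log2 change, between the bounds set beforehand for either reading. A pair of probes that both changed at least 4-fold entered from each side, as for Ctsc and Fcrla. Such pairs moved alike, so the share would be lower with each pair counted once. Fcrla, Ctsc, Gcnt1 and Cd79b moved alike on all their tested probes, whereas Zfp330, Mcm6, Ccdc93 and Scoc changed on 1 probe by at least 4-fold and by less than 0.5 of that on the others (examples chosen after their values were seen). Probe sequences and strain variants were not analysed here, so the 2 readings cannot be told apart for genes with 1 tested probe such as Ccng2, Cops8, Timmdc1 or Eif2s3y.

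By detection, 57 probes were read on 3 WT and 0 KO arrays and 176 on 0 WT and 3 KO arrays, a sum of 233 against at most 81 for any other split of the arrays. KO arrays detected more probes in general (13858 to 14026) than WT arrays (12948 to 13442), which favours the KO side. Many of the 176 lay near the detection limit and did not pass with limma, such as Cpsf3 (at least 1.00-fold, adjusted p = 0.577, chosen after its values were seen).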
